A study of Mus musculus with 10 samples.

How the data were processed

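Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, on nuclei from both cochleae of single CD1 mice at postnatal day 2 (P2, 3 animals), day 5 (P5, 3 animals) and day 8 (P8, 4 animals). Per the labels' protocols, tissue of each animal was homogenised, nuclei were purified on an iodixanol gradient, and transposition followed the Omni-ATAC protocol. The labels describe no sort or enrichment of a cell type, so the nuclei came from the whole dissected tissue.

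The submitters' processing notes name Trimmomatic 0.33, Subread 1.4.6-p3, MACS2 2.1.0 and the mouse build mm10, without their settings. The files used here are 3 deposited peak lists, 1 per age, with no list per animal. Each has 20 columns in the layout written by the irreproducible discovery rate (IDR) method, which keeps peaks whose order agrees between 2 input lists. The authors' ranking value of a peak in the deposited lists is on the −log10 p-value scale, and in every line it equals the smaller of the values of the 2 inputs. The IDR score of each peak in the deposited lists reached an IDR of at most 0.05. Which animals or pools formed the inputs is not given in the sources used here, so the inputs were not treated as replicates. All peaks were 499 bp wide. How reads were shifted for the transposase, filtered or pooled is not given in the sources used here. The lists hold no read counts, so the depth of each sample is unknown from these files, and a deeper sample can yield a longer list. Ranking values are the authors' own and were used only to order peaks within a list. A peak's place is given as its within-list percentile, with 100 at the top.

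From these lists, peaks overlapping by at least 1 bp were merged into regions, each called or not called at each age. A region called at P8 and not at P2 was termed gained, and the reverse lost. The same terms were used for the steps P2 to P5 and P5 to P8. Shares are given with Wilson 95% intervals, which cover counting error only. With 1 list per age there is no spread between animals, so no p-value was computed for any comparison. Overlap between lists was set beside lists moved along their chromosomes by a random offset in 100 draws.

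Gene positions came from a RefSeq table of assembly GRCm38.p6, the same build as mm10, with 21887 protein-coding genes on the chromosomes used. That table gives gene starts and ends but no strand, exons or sequence. The planned distances to transcription start sites were therefore replaced by distances to gene bodies and gene ends. Exon and intron shares and the planned search for transcription factor motifs were not run. Starts in the lists were read as counted from 0 and are printed counted from 1, which is uncertain by 1 bp because the lists do not state it. Each region was assigned to the nearest protein-coding gene within 100 kb, at distance 0 inside a gene. Of all regions, 91.3% had such a gene. A region was near a gene end if its middle lay within 1 kb of either end of any annotated gene. A gene's net gain is its gained minus its lost regions.

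Lists of genes for cochlear cell types, other tissues that a dissection can hold, and developmental programmes were fixed before the data were examined, as were the comparisons. Of their 452 symbol entries, 447 matched a protein-coding gene. Each of the 23 lists' summed net gain per 100 regions was placed among 10000 random gene lists of the same size, matched on regions per gene in 10 strata. A list outside the central 95% is said to stand apart. Chance alone would put 1.15 of 23 lists there. These percentiles describe these 3 lists and are not p-values.

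The named genes followed a rule set before the data were examined. It took Gjb2 and Gjb6, and the 10 genes with the highest and the 10 with the lowest net gain from P2 to P8. It also took up to 2 members of each list in each direction with a net gain of at least 2 either way. The last were the genes nearest to the 5 highest-ranked peaks of each list lying more than 1 kb from gene ends. Some genes that this rule takes are not reported here. Members named outside that rule were chosen after their values were seen, and are the further members of the bone, thyroid hormone, Hox, Schwann cell and gap junction lists, and the members of gene families.

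Alternatives were other overlap rules, only the upper 50% of each list, lists of equal length (the top 43878 peaks of each), changes that P5 supports, other distances and rules for assigning genes, and unmatched random lists. For genes and gene lists, the upper 50% of one age was set against all peaks of the other age. Changes that P5 supports are gained or lost regions that were also called at P5. This rule leaves out regions already lost at P5, so a lower count under it does not speak against such losses. After the list results were seen, the regions of the lists that stood apart and of the Gjb2 window were also set against 10000 draws of regions from the same age, matched on rank in 20 bins and on nearness to a gene end. The same excess was also placed among random gene lists, or for Gjb2 among windows around protein-coding genes. The windows keep neighbours together. The random lists keep only regions of the same gene together and draw genes from across the genome, so they do not allow for neighbouring genes. The rank draws and these percentiles were repeated with regions up to 500 bp apart merged. The lists were chosen for the same gains and losses that these draws count, which the percentiles do not allow for. The list procedure was tested on simulated gains and losses over 15803 genes in lists of 20 genes, with each region drawn independently. Of 400 lists with no planted effect, 2.0% fell above the central 95% and 2.2% below it. Of 20 lists with 2-fold more gained and also 2-fold fewer lost regions, 90.0% were found above it. Of 20 with 3-fold more gained and 3-fold fewer lost regions, 100.0% were. The simulation linked no neighbouring genes, so it does not show how often lists of neighbouring genes fall outside by chance. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.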

Results

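Open chromatin was mapped in the whole cochlea of CD1 mice, an outbred stock, at 3 ages before the onset of hearing, with 3 animals at P2, 3 at P5 and 4 at P8. The design asks which regulatory elements are used during this part of development, in a study on cell-specific delivery of GJB2, the gene of the gap junction protein connexin 26. The deposited lists held 52085 peaks at P2, 47683 at P5 and 43878 at P8, covering 26.0, 23.8 and 21.9 Mb. Each age is represented by 1 list, so differences between ages have no replicate check. The median ranking value, on the authors' −log10 p-value scale, was 57.8 at P2, 34.1 at P5 and 29.7 at P8, and an IDR of at most 0.01 was reached by 84.6%, 81.9% and 81.0% of peaks. The lowest ranking value in each list was 19.5 at P2, 13.5 at P5 and 11.4 at P8, so the weakest peak called differed between ages. Among the peaks kept in each list, the values of the 2 inputs had a Spearman correlation of 0.955, 0.932 and 0.927 across peaks, which are not independent replicates. The IDR method keeps peaks whose order agrees, so these values do not measure how well the whole input lists agreed.

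Most accessible regions of the cochlea were shared between ages. The 3 lists merged into 64911 regions, of which 32681 (50.3%, 95% interval 50.0 to 50.7) were called at all 3 ages. Regions called at a single age numbered 10283 at P2, 4151 at P5 and 4811 at P8. Between P2 and P8, 34937 regions were kept, 16973 were lost (32.7% of those called at P2, 32.3 to 33.1) and 8850 were gained (20.2% of those called at P8, 19.8 to 20.6). Of the regions gained or lost, 65.7% were losses. That excess equals the difference between the numbers of regions called at P2 (51910) and at P8 (43787), so it says nothing beyond the length of the lists. When each list was shortened to the same number of peaks, which imposes a balance, 10903 regions were lost and 10943 gained.

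**Figure D1:**
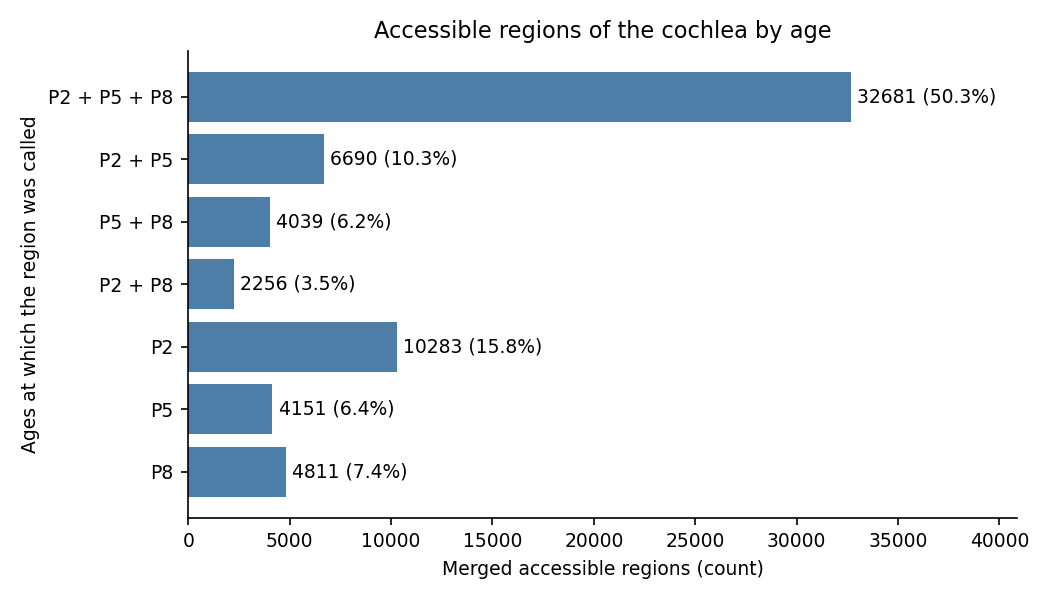
Number of merged accessible regions (horizontal axis, count) for each combination of ages at which they were called (vertical axis), with the percentage of all 64911 regions beside each bar. Regions called at all 3 ages form the longest bar, with 32681 regions, and those called at P2 and P8 but not at P5 the shortest, with 2256.

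Regions that were gained or lost lay mostly away from gene ends. Of kept regions, 36.3% (35.8 to 36.8) lay within 1 kb of a gene end, against 15.4% (14.8 to 15.9) of lost and 10.3% (9.67 to 10.9) of gained regions, and 6.34% of regions moved to random places. Regions inside protein-coding genes made up similar shares of kept, lost and gained regions, at 52.9%, 54.5% and 53.6%. The regions called at all ages were also the stronger ones, with median within-list percentiles of 67.8, 65.0 and 61.6 at P2, P5 and P8, against 16.7 for regions called at P2 alone, 13.5 at P5 alone and 15.7 at P8 alone. Of regions called at P2 and P8, 6.46% (6.20 to 6.72) were not called at P5, and 1 list per age does not show whether these were missed or closed for a time. By comparison, 11% (10.7 to 11.3) of regions called at P5 and P8 were not called at P2, and 16.99% (16.6 to 17.4) of those called at P2 and P5 were not called at P8. At equal list length these shares were 6.07%, 13.3% and 13.1%.

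The overlap of the lists was far above that of shifted lists. A P8 peak overlapped 67.3% of P2 peaks, a P5 peak overlapped 75.8% of P2 peaks and a P8 peak overlapped 77.2% of P5 peaks, while shifted lists gave medians of 1.75%, 1.90% and 1.76%. The highest-ranked regions more than 1 kb from a gene end recurred between ages. A region on chromosome 1 at 7088592 to 7089091, inside Pcmtd1, ranked 9 at P2, 7 at P5 and 34 at P8. One inside Trim45 on chromosome 3, at 100922035 to 100922533, was among the 5 highest at all 3 ages, with ranks of 13, 45 and 84. The others among the 5 highest of a list lay inside Fer, Ddx50, Ybx1, Rps6ka2, Aktip and Hdac4, except 1 on chromosome 8 at 20122045 to 20122550 with no protein-coding gene within 100 kb. All of these regions were called at all 3 ages. Those inside Pcmtd1, Trim45, Fer, Ybx1 and Aktip lay within 2.5 kb of an end of that gene, so they are not far from gene ends.

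From P2 to P8, bone genes gained more accessible regions than they lost. The osteoblast and bone list had 26 gained and 8 lost regions (32 and 7 at equal list length), so that 76.5% (60.0 to 87.6) of its regions gained or lost were gains, against 33.5% (32.9 to 34.1) over all 15803 genes with regions. Its net gain of 21.7 per 100 regions lay at percentile 100.0 of the random lists, whose median was −12.9. Of its 16 genes with regions, 12 had a net gain, 1 a net loss and 3 neither. Ibsp, which encodes bone sialoprotein, had no region at P2, 2 at P5 and 4 at P8, and Dmp1, the gene of a matrix protein of bone and dentin, had 1, 2 and 4. Phex, whose product regulates phosphate handling in bone, gained 3 regions and lost 0. The exception was Col1a1, the gene of a chain of type I collagen, with 0 gained and 2 lost.

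Several of these bone genes lie side by side on chromosome 5. Within 50 kb of the stretch from Dmp1 through Ibsp and Mepe to Spp1, 10 regions were called at P2, 12 at P5 and 19 at P8, with 11 gained and 2 lost. A gained region at 104149202 to 104149700 lies beside a lost region at 104149806 to 104150304, a pair that a shifted peak would also give. The gained regions highest in the P8 list lay between Dmp1 and Ibsp, at 104261849 to 104262419 (within-list percentile 73.7 at P8 and 64.3 at P5) and at 104271132 to 104271760 (66.1 and 42.6), and neither was called at P2. Another, at 104299002 to 104299500, lay at the lower-coordinate end of Ibsp and was called only at P8. The bone list's place was lower with only the changes that P5 supports (95.4) and with only peaks of the upper 50% of a list counted (73.6, with 2 gained and 2 lost). Of its 26 gained regions, 24 lay in the lower 50% of the P8 list. Regions matched on rank gave 12 to 25 not called at P2, against these 26 (percentile 98.3). Without Dmp1, Ibsp, Mepe and Spp1 the number was 16 of 54, inside the 8 to 20 of matched regions (78.8).

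**Figure D2:**
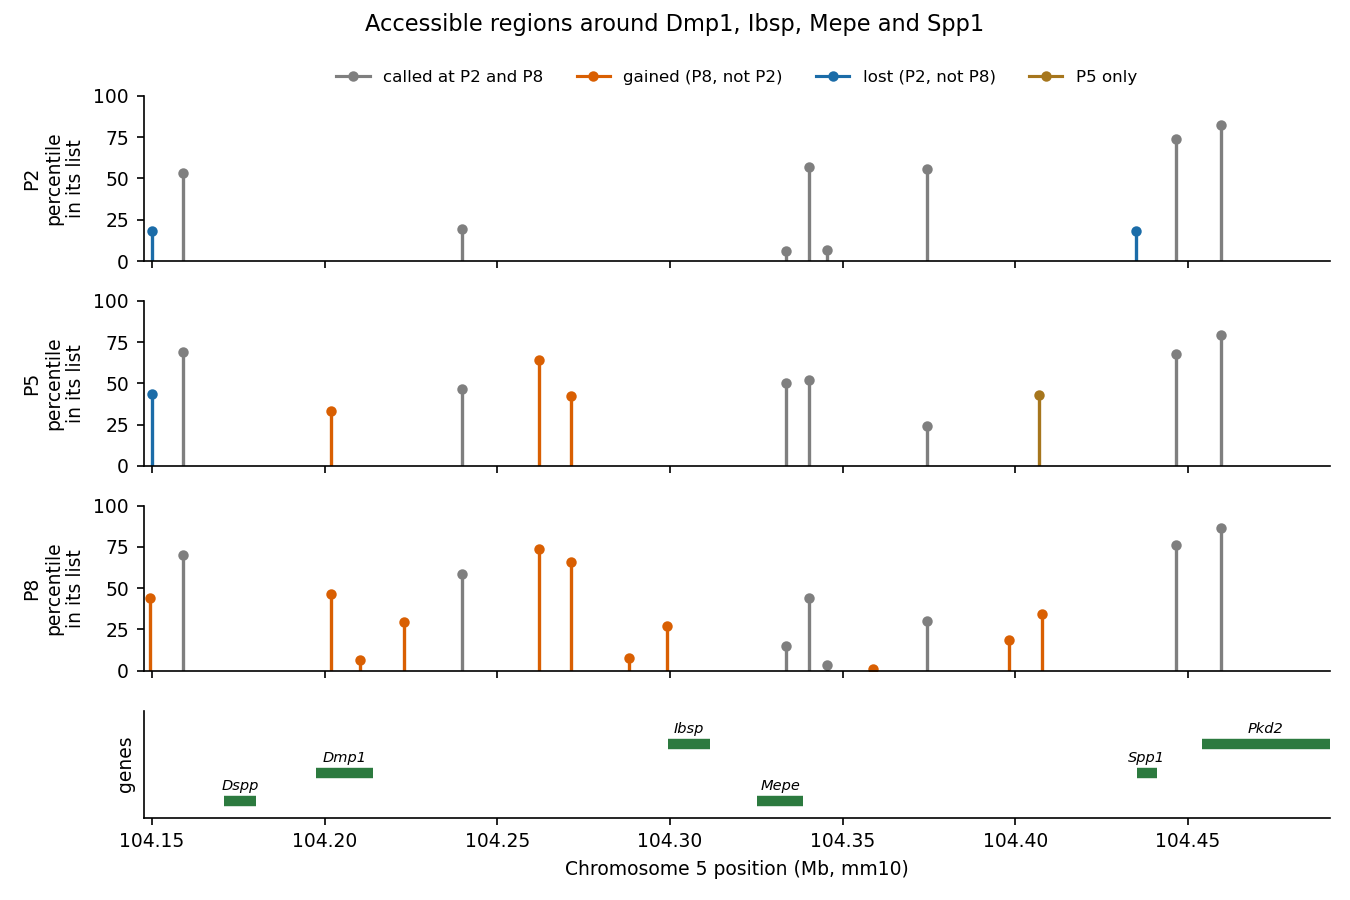
Accessible regions on chromosome 5 around Dmp1, Ibsp, Mepe and Spp1 (horizontal axis, position in Mb), with 1 panel per age and the height of each line giving the region's percentile within that age's own list, and protein-coding gene bodies below. The window holds 11 regions called at P8 and not at P2 and 2 called at P2 and not at P8.

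**Figure D3:**
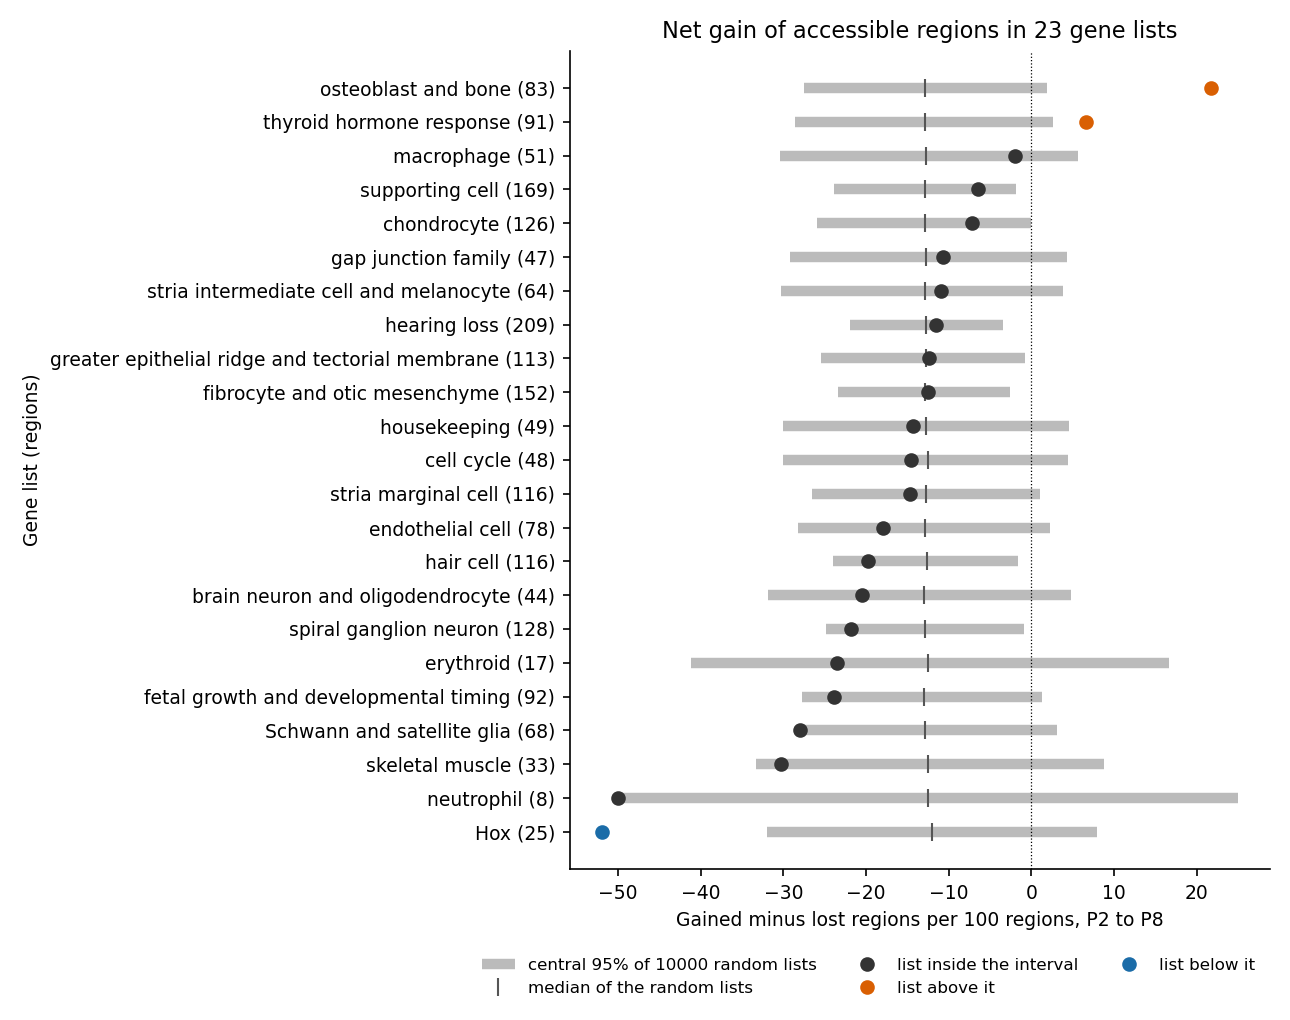
Gained minus lost regions per 100 regions from P2 to P8 (horizontal axis) for the 23 gene lists (vertical axis, number of regions in parentheses), as points, over the central 95% and the median of 10000 random lists. Bone (21.7) and thyroid hormone response (6.59) lie above their interval and Hox (−52.0) lies below it.

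The thyroid hormone response list also stood apart upward, with 20 gained and 14 lost regions (23 and 9 at equal list length), a net gain of 6.59 per 100 regions and percentile 99.4. Of its 14 genes with regions, 5 had a net gain, 4 a net loss and 5 neither. Thrb, which encodes thyroid hormone receptor beta, had 15 regions at P2, 19 at P5 and 20 at P8, with 8 gained and 3 lost, and all but 1 of the gained regions lay inside the gene. Nrgn had 3 gained and 0 lost, whereas Rxrg, a retinoid X receptor gene, had 0 gained and 2 lost. The list's place rested on Thrb, since it was 94.8 without that gene. It was 75.1 with only the changes that P5 supports and 93.2 with only peaks of the upper 50%, and its 20 P8 regions not called at P2 lay inside the 10 to 22 given by regions matched on rank (percentile 88.9).

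The Hox genes, which encode transcription factors that pattern the body axis, stood apart downward. They had 25 regions at P2, 12 at P5 and 12 at P8, with 0 gained and 13 lost between P2 and P8 (percentile 0.01), and 0 and 9 at equal list length. Of the 19 Hox genes with regions, 12 had a net loss and none a net gain in the full lists. From P5 to P8 they had 4 gained and 4 lost (73.0), and the 4 gained regions had been called at P2. The regions lie in 4 clusters and are not independent of each other. The place was 3.97 with only the changes that P5 supports, which leaves out regions already lost at P5. It was 6.04 with only peaks of the upper 50%. The 13 losses lay inside the 6 to 14 given by P2 regions matched on rank (percentile 89.5).

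Lists of the sensory epithelium did not stand apart from P2 to P8 with each region given to its nearest gene. The hair cell list had 14 gained and 37 lost regions (percentile 11.2, but 0.18 and so outside the interval when regions within 50 kb were counted for every gene), with 4 of 32 genes gaining and 16 losing on balance. Myo7a, an unconventional myosin of the hair bundle, and Otof, needed for transmitter release by inner hair cells, each had 0 gained and 3 lost, while Ikzf2, a transcription factor gene of outer hair cells, had 2 gained and 0 lost. The supporting cell list had 34 gained and 45 lost (87.1). In it Id2 gained 4 and lost 0, whereas Lgr6 gained 2 and lost 9 and Hes1, a Notch target, gained 3 and lost 7. At equal list length Lgr6 kept 2 and 9, but Hes1 had 3 and 4. The list for the greater epithelial ridge and tectorial membrane, a transient epithelium and the matrix it secretes, had 19 gained and 33 lost (52.9). Ceacam16 had a net gain of 2 and Dkk3 of −4. Itga8 had 2, but −1 with only the changes that P5 supports, and Tecta had −3, but 1 at equal list length. The gap junction list had 8 gained and 13 lost (59.0), with Gja5 at 2 and Panx1 at −2, and the hearing loss list 34 and 58 (60.5), with Myh14 at −3.

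Lists of the lateral wall, connective tissue and nerve lay inside the random interval from P2 to P8 under the same assignment. The marginal cell list of the stria vascularis had 15 gained and 32 lost regions (percentile 39.7), with Kcnq1, a potassium channel of these cells, at −6 and Shroom3 at −2. At equal list length Kcnq1 was at −1 and Shroom3 at 2. The intermediate cell and melanocyte list had 8 and 15 (58.4), with Slc24a5 at 3 and Kit and Dct each at −2. The fibrocyte and otic mesenchyme list had 21 and 40 (52.5), with Postn at −5 and Tgfbi at −3, which was 0 at equal list length. Chondrocyte genes had 20 and 29 (80.5), with Sox5 and Matn1, both genes of cartilage, each at −4 (−1 and −2 at equal list length). Spiral ganglion neuron genes had 16 and 44 (7.36, but 1.62 within 50 kb), with Rbfox3 at −7 and Runx1 at −4. Schwann and satellite glia genes had 4 and 23 (2.74), with the myelin gene Mbp at −5 and Pou3f1 at −3, and were at 15.4 at equal list length.

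Apart from bone, which stood apart upward, markers of other cell types that the tissue can hold gave no list outside the interval of matched random lists from P2 to P8. Macrophage genes had 10 gained and 11 lost regions (percentile 88.8), with Ptprc at 3, and neutrophil genes 0 and 4 (2.82) from only 8 regions (0.92 against unmatched random lists), with Csf3r at −2 and Mmp9 at −2, the latter 0 at equal list length. Erythroid genes had 2 and 6 (23.9). Endothelial genes had 9 and 23 (26.1), with Cdh5 at −3 and Erg at −3, which was 1 both at equal list length and with only the changes that P5 supports. Skeletal muscle genes had 2 and 12 (4.80), with Myh3 at −3 and Myog at −2, and brain genes 4 and 13 (20.9), with Neurod6 at −3, Gad1 at −2 and Mobp at 2. The cell cycle list had 4 and 11 (41.1), with Mki67 at −2 and Mcm3 at −2, the latter 0 at equal list length. Genes of fetal growth and developmental timing had 10 and 32 (6.48, but 1.98 within 50 kb), with Dlk1 and Hmga2 each at −6. Housekeeping genes had 5 and 12 (43.0), with Eef1a1 at −2, which was 0 at equal list length. At equal list length, gains outnumbered losses in the supporting cell, intermediate cell, fibrocyte, chondrocyte, macrophage and hearing loss lists, so the direction of those lists depends on list length. Among genes named from the lists, the net gain was 0 with only the changes that P5 supports for Hmga2, Id2, Ikzf2, Mcm3, Mmp9, Mobp, Myog, Neurod6, Nrgn and Otof. It was 0 for Cdh5 and Ceacam16 within 50 kb, for Cdh5 and Pou3f1 within 20 kb, and for Shroom3 and Sox5 by nearest gene end. The lost regions of Hmga2, Mcm3, Mmp9, Myog, Neurod6 and Otof were called at neither P5 nor P8. The rule on P5 leaves such losses out and does not speak against them.

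Single genes differed widely in their balance of gained and lost regions from P2 to P8. Arhgap26 had 12 gained and 5 lost regions, Lpar1, a lysophosphatidic acid receptor gene, 9 and 2, and Syn3, which encodes synapsin III, 9 and 2. Rgs6 had a net gain of 6, as had Banf2, Kif16b and Syt13, each with 6 gained and 0 lost. Thrb, Lifr, the gene of the leukaemia inhibitory factor receptor, and Bbs9 each had a net gain of 5. The lowest was Cux1, a homeodomain transcription factor gene on chromosome 5, with 22 regions at P2, 13 at P5 and 4 at P8. Its 0 gained and 18 lost regions were followed by the 4 gained and 16 lost of Wwox. Chst15, Tiam1, Zfp423, Agap1 and Megf6 had a net gain of −11, and Tns1, Disc1 and Cachd1 of −10. The ranking is by count and not by share, so it favours genes with many regions, such as Arhgap26 (41) and Wwox (37). Over all genes, 7688 of 59245 assigned regions were gained and 15252 lost, so a negative net is expected of a gene with many regions. These 20 genes kept their direction at equal list length, and none has an error of its own. All of the 10 lowest were then less negative, with Wwox and Zfp423 at −3, Chst15 and Cachd1 at −4, and Tiam1, Agap1 and Tns1 at −5. None of the 10 highest was then lower. The net gain was 0 for Arhgap26 with only the changes that P5 supports, for Arhgap26, Syn3 and Rgs6 by nearest gene end, for Lifr within 20 kb, and for Rgs6, Kif16b, Cux1, Tiam1 and Disc1 with only peaks of the upper 50%. Among genes of the highest-ranked regions, Rps6ka2 was at −4, Pcmtd1 at −1 (0 at equal list length) and Hdac4 at −2 (2 at equal list length).

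Some lists stood apart in only 1 of the steps between ages. From P2 to P5, 12539 regions were lost and 8190 gained. Schwann and satellite glia genes stood apart downward, with 4 gained and 26 lost regions (percentile 0.04, but 11 gained and 8 lost at 92.2 from P5 to P8), as did Hox genes, with 0 and 13 (0.0), and endothelial genes, with 8 and 25 (2.27). Genes of the greater epithelial ridge and tectorial membrane stood apart upward, with 23 and 16 (99.1). From P5 to P8, 10841 regions were lost and 7067 gained. The bone list stood apart upward, with 23 gained and 9 lost (99.96, and 12 and 8 at 96.7 from P2 to P5), while the greater epithelial ridge list, with 12 and 33 (0.59), and the spiral ganglion neuron list, with 11 and 32 (1.205), stood apart downward.

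In all, 7 of 46 list results of the steps stood apart, where chance would give 2.3. Whether a list differed between the steps was not tested, and both steps share the P5 list, so a list can be high in one and low in the other through P5 alone. At equal list length the endothelial list (12.98), the greater epithelial ridge list (91.3 and 5.17) and the spiral ganglion list (5.70) no longer stood apart. With only peaks of the upper 50% counted, neither did bone from P5 to P8 (63.3), Hox from P2 to P5 (53.85), each with 0 gained and 0 lost, nor the endothelial (8.02), spiral ganglion (40.5) and, from P5 to P8, greater epithelial ridge (35.2) lists. Against regions matched on rank, the counts of Schwann cell losses (percentile 99.7), Hox losses (99.6) and bone gains (99.2) in these steps lay above the central 95%. Without Dmp1, Ibsp, Mepe and Spp1, bone gains were at 92.2. Endothelial losses (96.8), greater epithelial ridge gains (74.1) and losses (94.5) and spiral ganglion losses (87.1) lay inside the central 95%. Greater epithelial ridge losses were at 98.1 with regions of the same gene kept together and regions up to 500 bp apart merged.

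Around Gjb2, more regions were gained than lost between P2 and P8. Gjb2 lies on chromosome 14 at 57098602 to 57104702 in mm10, and Gjb6, which encodes connexin 30, next to it at 57123301 to 57133611. Within 200 kb of Gjb2 there were 23 regions, with 12 called at P2, 12 at P5 and 17 at P8. Of these 7 were called at all ages, 9 were gained and 4 lost, so that 69.2% (42.4 to 87.3) of those gained or lost were gains, an interval that includes an even split. At equal list length 10 were gained and 3 lost. With only the upper 50% of each list, 2 were gained and 0 lost, but 1 of these 2, at 57248547 to 57249061, was called at all ages in the full lists.

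The region highest in the P2 list within this window lay across the higher-coordinate end of Gjb2, at 57104442 to 57104940, and was called at all ages (within-list percentiles 75.4 at P2, 63.1 at P5 and 70.5 at P8). Of the 6 regions called only at P8, 3 lay 1.2 kb below the lower-coordinate end of Gjb2, at 57096908 to 57097406, between Gjb2 and Gjb6 at 57113756 to 57114254, and across the higher-coordinate end of Gjb6 at 57133177 to 57133675, with P8 percentiles of 18.5, 29.7 and 5.3. The other 3 lay farther away, at 57165502 to 57166000, 57241808 to 57242306 and 57249684 to 57250182 (10.0, 0.8 and 21.6). A region at 57161757 to 57162299, 57.1 kb from Gjb2 and beyond Gjb6, was called at P5 and P8 (19.5 and 44.6), but it lies beside a region called only at P2, at 57161121 to 57161619 (40.8), a pair that a shifted peak would also give. The other lost regions lay at 57057467 to 57057965, 57158352 to 57158850 and 57230606 to 57231104 (20.7, 3.5 and 39.6 at P2). The gained region highest in the P8 list (54.5, and 68.8 at P5) lay at 57257336 to 57257846, 152.6 kb from Gjb2 between Gjb6 and Cryl1. The remaining gained region (10.6, and 24.6 at P5) lay inside Cryl1 at 57301192 to 57301803, 196.5 kb from Gjb2. By nearest gene, Gjb2 had 1 gained and 0 lost regions (0 and 0 with only the changes that P5 supports) and Gjb6 had 4 gained and 2 lost. Of the Gjb6 changes, only the gained region at 57161757 to 57162299 was also called at P5. Nearness does not show which gene a region acts on.

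**Figure D4:**
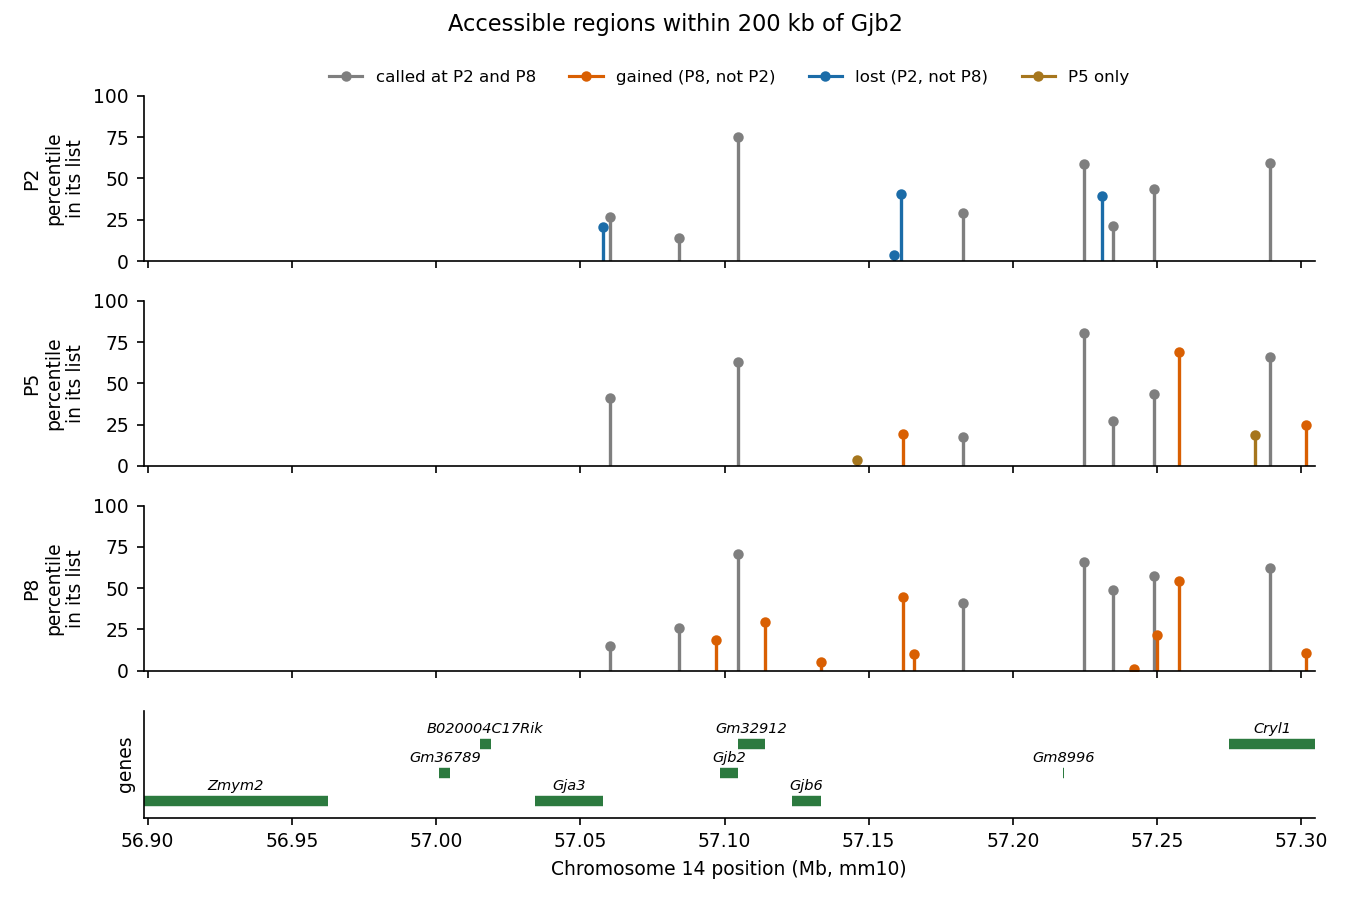
Accessible regions within 200 kb of Gjb2 on chromosome 14 (horizontal axis, position in Mb), with 1 panel per age and the height of each line giving the region's percentile within that age's own list, and gene bodies below. Of the 23 regions, 7 were called at all ages, 9 at P8 and not at P2, and 4 at P2 and not at P8.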

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

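The steps' alternatives, the nearest gene end, IDR of at most 0.01, autosomes only, the equal-length result of the Gjb2 window, merging across gaps of up to 500 bp, and the upper 50% set against all peaks of the other age for genes and lists were chosen after seeing the data. Over the fixed lists and their steps, 176 combinations of result and alternative kept their direction and side of the central 95%, 22 lost a place outside them, 4 gained one, and 1 (Hox from P2 to P5 with the upper 50%, where no region was gained or lost) passed the median of the random lists. The cause of these differences was not tested, except that fewer peaks enter with an upper 50% or equal lengths. Losses among regions gained or lost, 65.7% in the full lists, were 64.9% with 50% reciprocal overlap, 63.5% with centres within 100 bp, 68.3% with the upper 50% of each list, 66.3% with the upper 50% against all peaks, 70.1% at an IDR of at most 0.01 and 49.91% at equal list length, where the cut imposes a balance. Gained regions numbered 3550 and lost regions 7646 with the upper 50% of each list, 1058 and 2085 with the upper 50% against all peaks, and lost regions 10903 at equal length. Within 2.5 kb of a gene end lay 39.2%, 38.5% and 40.1% of regions at P2, P5 and P8, 18.8% of gained and 26.2% of lost regions, and with protein-coding genes alone 23.8%, 24.0%, 25.5%, 4.95% and 9.67% lay within 1 kb.

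Bone was at 95.4 with changes that P5 supports and 73.6 with the upper 50% against all peaks (63.3 from P5 to P8), thyroid hormone response at 75.1 and 93.2, and Hox at 3.97 and 6.04. From P2 to P5, Hox was at 53.85 with the upper 50%, where it had 0 gained and 0 lost regions. Endothelial genes were at 4.59 within 50 kb, 12.98 at equal length, 3.62 unmatched and 8.02 with the upper 50%. The greater epithelial ridge from P2 to P5 was at 93.8 within 50 kb, 91.3 at equal length and 97.4 unmatched, and from P5 to P8 at 5.56 within 50 kb, 3.76 within 20 kb, 5.17 at equal length and 35.2 with the upper 50%. Spiral ganglion genes from P5 to P8 were at 3.11 within 20 kb, 5.70 at equal length, 2.86 unmatched and 40.5 with the upper 50%. Within 50 kb, the hair cell (0.18), spiral ganglion (1.62) and fetal growth (1.98) lists also stood apart from P2 to P8, as did neutrophil genes (0.92) unmatched. The Gjb2 window had 2 gained and 0 lost regions with the upper 50% of each list, 1 of the 2 being called at all ages in the full lists. With regions up to 500 bp apart merged, 8284 regions were gained and 15952 lost, bone was at 100.0, thyroid hormone response at 99.3 and Hox at 0.0, and the Gjb2 window had 8 gained and 3 lost. Over the named genes, 155 net gains stayed as they were under an alternative, 304 took another size without turning and 8 turned. Of the 73 genes with a net gain other than 0, 39 were at 0 with the upper 50% against all peaks and 12 with changes that P5 supports. They turned for Erg (1 with P5 support and 1 at equal length), Hdac4 (2 with P5 support, 2 at equal length, 1 with the upper 50%), Itga8 (−1 with P5 support), and Shroom3 (2) and Tecta (1) at equal length. No paired analysis was possible because each age has 1 list, and leaving out an animal was not possible for the same reason. The motif alternatives were not run without a genome sequence. Unknown depth limits each statement on a region not called.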

Other observations

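The gene families, the windows around protein-coding genes, the list length test at Gjb2, the test of the chondrocyte list, and that of the brain and muscle lists were chosen after the results were seen. So were the rank tests of Hox losses up to P8 and of bone outside the cluster, and the tests of shifted peaks and with neighbours or regions of the same gene kept together. Of 39 families formed by gene symbol, 9 stood apart from P2 to P8, where chance would give 1.95, and 6 of these also did so in the same direction at equal list length. The families were not set against regions matched on rank, so weak peaks were not checked for them. Glutamate receptor genes had 7 gained and 53 lost regions (percentile 0.0), and 13 and 35 at equal list length (0.05). Of 22 genes, 18 had a net loss and 1 a net gain, with Grik4 at −8 (−2 at equal length), Grik3 at −6 (−4), Grin2b at −6 (−5) and Grm4 at −6 (−1). Ephrins and Eph receptors, which guide axons and set tissue boundaries, had 5 gained and 51 lost (0.03), and 8 and 32 at equal length (0.07), with 17 of 22 genes losing, among them Ephb2 at −8 (−2 at equal length) and Epha2 and Ephb1 at −6 (−4 each).

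Collagen genes had 36 gained and 117 lost regions (0.03), and 48 and 80 at equal length (0.17), with Col4a2 at −7 (−3 at equal length), Col6a3 and Col27a1 at −6 (−5 each) and Col23a1 at −6 (0). Wnt ligand genes had 8 and 38 (0.57), and 9 and 21 at equal length (2.12), with Wnt11 at −5 (−4). Genes whose symbol is Fgf and a number had 4 and 19 (2.35), and 5 and 15 at equal length (1.32). In the other direction, Klf transcription factor genes had 24 gained and 18 lost regions (99.8), and 26 and 7 at equal length (99.7). Klf12 was at 5 and Klf13 at 3, but only 6 of 17 genes had a net gain, and Klf15 turned from −2 to 1 at equal length.

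The 200 kb around Gjb2 stood out, with a net gain of 5 against a median of −3.0 in 5034 windows with a similar number of regions around protein-coding genes (percentile 99.4). Windows of adjacent genes overlap, so they are not independent comparisons. Unequal list length is argued against as the whole cause, since at equal length the net was 7 against a median of 0.0 (percentile 99.25 of 5467 windows). Equal length does not equalise the weakest peak called. The lowest ranking value in the full lists was 19.5 at P2 and 11.4 at P8, so a gained region is not shown to have been closed at P2. Weak peaks near the P8 threshold are argued against only weakly as the whole cause. Of the window's 17 P8 regions, 9 were not called at P2, where draws matched on rank gave 2.0 to 8.0 (percentile 98.65). The place was 99.35 among windows around protein-coding genes, which keeps neighbours together. That margin is 1 region, 8 of the 9 lay in the lower 50% of the P8 list, and weak peaks together with a shifted peak stay open, since with regions up to 500 bp apart merged, 8 of 17 lay inside the draws (96.68) and outside the central 95% of windows (98.45). Further opening of this stretch with age is open as well, and cannot be told apart from that combination. Several of the gained regions, among them the highest in the P8 list, had Cryl1 as nearest gene, which is not a connexin gene.

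Bone genes gained regions at percentile 100.0. Over the whole list, 26 of 70 P8 regions were not called at P2, against 12 to 25 in matched draws (98.3). The place was 98.66 with regions of the same gene kept together, and 99.2 in draws with shifted peaks merged. The list was 1 of 23 and was taken up for these same gained regions. Its excess over the draws therefore does not decide whether weak peaks near the P8 threshold were the only cause. The margin over the draws is 1 region, and without the neighbours Dmp1, Ibsp, Mepe and Spp1 the number was 16 of 54, inside the 8 to 20 of matched draws (78.79), so weak peaks could account for the gains outside that cluster. Without matching on rank, the list without them was still at 99.9, so the cluster is not the whole cause of the list's place. More skeletal tissue in the older samples may have added these regions, and the chondrocyte list at 80.48 neither shows nor excludes that, as no sort removed bone and 2 of the bone list's 17 genes (Col1a1 and Col1a2) are also in the fibrocyte list. Ossification of the cochlear capsule with age is the open biological alternative and cannot be told apart from the share of bone in the samples.

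Hox genes had 25 regions called at P2, of which 13 were not called at P5 and 4 of those were called again at P8, which goes against a lasting closing with age for those 4. For the P5 count, matched draws gave 4 to 12 (percentile 99.57, 99.94 with regions of the same gene kept together, and 99.7 in draws with shifted peaks merged). None of these keeps the genes of a Hox cluster together. The list was 1 of 23 and was taken up for its losses, which this test counts again, and all 13 lay in the lower 50% of the P2 list. The test therefore does not decide whether weak peaks near the P2 threshold were the whole cause of the P5 count. For the 13 not called at P8, weak peaks could account for the number, with 6 to 14 in matched draws (percentile 89.45, and 94.65 with regions of the same gene kept together). Tissue from outside the cochlea in the P2 samples stays open, with the skeletal muscle (4.35) and brain (23.88) lists from P2 to P5 inside the central 95%. A loss shared by developmental homeobox genes also stays open, with homeobox genes outside the clusters at 2.75 from P2 to P5, 1.73 from P2 to P8 and 4.52 at equal list length, and with 1 list per age these cannot be told apart from age itself.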
